A study of Homo sapiens with 12 samples.

How the data were processed

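The 12 libraries came from HEK293T cells cross-linked with 1% formaldehyde for 10 minutes and quenched with 125 mM glycine, per the labels' protocols. Lysates were treated with ssRNase or dsRNase before protein was removed (footprints) or after protein had been removed with 1% SDS and proteinase K (digestion controls), and cross-links were reversed at 65 degrees for 2 hours. Libraries were normalised with a duplex-specific nuclease, per the labels' protocols. This step lowers abundant sequences, and its effect on the lists was not measured here.

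Adapters were trimmed with cutadapt 0.9.5 and TopHat2 2.0.9 was used with build hg19, per the submitters' processing notes. Sites were called with CSAR at a false discovery rate of 5%, as the names of the deposited lists state. Normalisation before calling, read filters and the handling of reads that map to several places are not given in the sources used here. Each of the 6 replicate lists compares a footprint library with its digestion control, per the labels, so that the 12 libraries enter through 6 lists. The 3 merged lists were made by the authors from the replicate lists, and each merged site names the replicate sites behind it.

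The deposited site positions were read as 1-based and inclusive, since starts reach 1 and some sites start and end on the same position. The score is a value per site deposited by the authors. Its scale is not given in the sources used here, so it was used only to rank sites within a list. The files hold no read counts, so no count model was used and the depth behind a site is unknown. A share of site bases corrects for the length of a list, not for the depth of its libraries. The authors' site names carry running numbers that go on beyond the listed sites.

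The reference tables at hand belong to another build than the lists, and coordinates were not converted. Gene names, the location of sites within transcripts, base composition and the 14 gene lists fixed before the data were examined were therefore not analysed here. As fixed beforehand for this case, stranded windows of 10000 bp took the place of genes, and shares per chromosome and strand the place of transcript location. A site belongs to the window of its midpoint.

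Numbers of sites, median lengths and shares were compared between the 3 lists of each nuclease by a two-sided exact permutation test, whose smallest p is 0.1, so that no such test could pass 0.05. Shares were adjusted by the Benjamini-Hochberg method over 28 chromosome classes and strand. Overlap was at least 1 nt on the same strand, and the expected overlap came from 100 draws in which each site was moved by 200 to 1000 nt (20 draws for alternatives). Windows were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options) on log2(site bases per 1000000 site bases of the list + 20), with an adjusted p of 0.05 as the threshold and a site in at least 3 of 6 lists as the filter. This filter admits windows with sites in all ssRNase lists and none in the dsRNase lists. Differences on this scale understate changes of low windows. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

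Named windows followed a rule fixed before the data were examined: the 10 largest differences in each direction among windows that passed and whose values did not overlap between nucleases, the 10 windows with the largest mean share, and the 5 longest sites found in all 6 lists.

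The overlap code was tested on simulated data against a base-by-base count, and 0 of 12000 calls differed. The window test was tested on simulated lists and performed poorly when few windows were changed. A first simulation with 200 changed windows gave 0 limma calls at 4-fold, 2-fold, 0.5-fold and 0.25-fold, at real and at equal list lengths. At real lengths 88.0%, 22.0%, 18.0% and 60.0% had an unadjusted p below 0.05. A second one, with lists drawn from ssRNase sites and 200 windows changed 4-fold, 16-fold, 0.25-fold or 0.0625-fold, gave 0 calls at the real list lengths and 1 at equal lengths. At the real lengths an unadjusted p below 0.05 was reached by 72.0%, 98.0%, 62.0% and 88.0% of these windows. A later simulation, designed after these results had been seen, changed 8000 windows. Among changed windows that kept a site in at least 3 lists, it recovered 459 of 1949 (23.6%) at 4-fold and 928 of 1936 (47.9%) at 16-fold. At 0.25-fold it recovered 129 of 1667 (7.74%) and at 0.0625-fold 374 of 1077 (34.7%). Changed windows lost to the filter, most of them at 0.0625-fold, are left out of these shares. Recovery among all changed windows was therefore lower. This simulation falsely called 132 of 25779 unchanged windows, all higher with ssRNase. At 200 changed windows the test thus did not recover what was simulated. The number of calls therefore depends on how many windows differ. In the second simulation at the real lengths 6.59% of unchanged windows leaned to ssRNase and 0.849% to dsRNase at an unadjusted p below 0.05. At equal lengths these shares were 1.93% and 1.92%, so unequal lengths gave a lean to ssRNase there. Both simulated nucleases were drawn from ssRNase lists, so other effects of list length in the data, also toward dsRNase, were not measured.

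Alternatives fixed before the data were examined covered the overlap rule, the strand, the expected overlap, the joining of nearby sites, the better-scoring 50% of sites, pseudocounts of 5 and 80 per 1000000, the window filter, the scaling, equal numbers of sites (21561 per list), a replicate block and leaving out each list. Leaving out a list was first run with the filter applied again to the remaining lists. A version that keeps the windows of all 6 lists was added after those counts had been seen. Also added after seeing the data were windows with a site of both nucleases, scaling or drawing within each strand (4987 plus-strand and 16574 minus-strand sites per list), each strand alone and half-open positions.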

Results

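RNA-protein contacts were mapped in HEK293T cells, an established human embryonic kidney line, by protein interaction profile sequencing. In this assay cells are cross-linked with formaldehyde, the lysate is digested with a ribonuclease, and RNA stretches shielded by protein survive and are sequenced. A digestion control, in which protein is removed before the nuclease is added, shows which stretches resist the nuclease without protein. Digestion was with RNase ONE, which cuts single-stranded RNA (ssRNase), or with RNase V1, which cuts paired RNA (dsRNase). The 12 libraries form 4 groups of 3 replicates, a footprint and a digestion-control group for each nuclease. Each footprint library was compared by the authors with the control of the same nuclease and replicate number, which gave 6 replicate lists of protein-protected sites, and 3 merged lists. Read depth is unknown, since the lists hold positions and scores but no read counts. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. All positions are hg19 as listed by the authors.

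The first comparison asked how much protected RNA each nuclease revealed. The ssRNase lists held 209922, 57481 and 172079 sites and the dsRNase lists 23925, 28413 and 21561 sites. The mean was 146494 ± 79376 sites with ssRNase (SD, n = 3) and 24633 ± 3480 with dsRNase (SD, n = 3), a ratio of 5.95. Every ssRNase list was longer than every dsRNase list (two-sided exact permutation p = 0.1, the smallest that 3 against 3 lists allow). The ssRNase lists differed widely among themselves, and replicate 2 was the shortest. Sites were longer with ssRNase, with a median of 43.0 ± 1.0 nt (SD, n = 3), than with dsRNase, with 33.33 ± 0.577 nt (SD, n = 3; two-sided exact permutation p = 0.1). The longest single site was 982 nt in ssRNase replicate 1 and 1172 nt in dsRNase replicate 2.

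**Figure D1:**
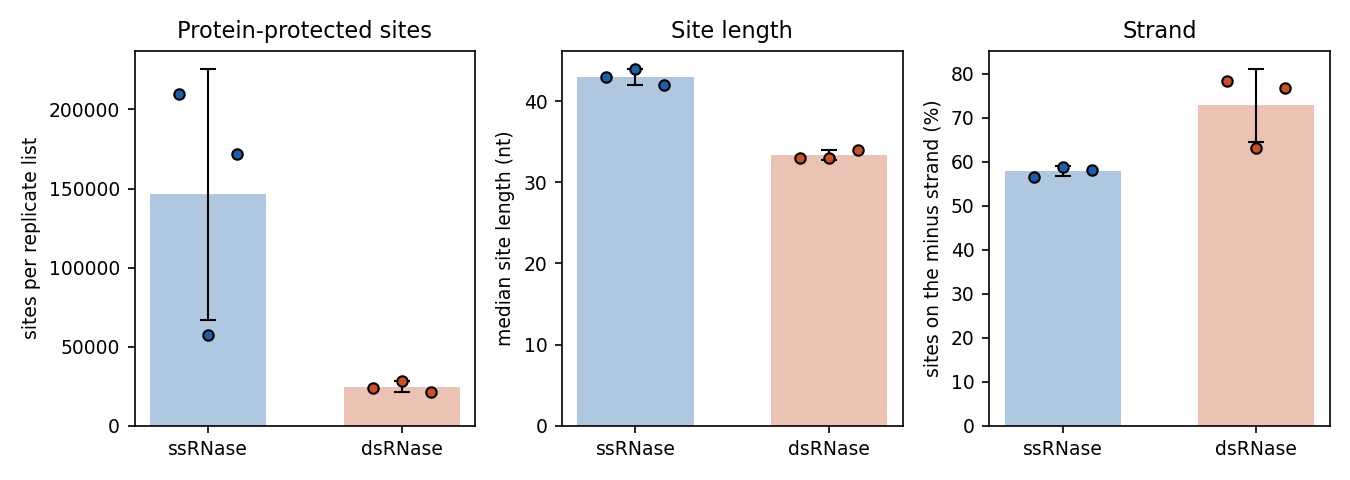
Number of protein-protected sites per replicate list, median site length in nt and percent of sites on the minus strand, for the ssRNase and dsRNase lists. Points are the 3 replicate lists, bars their mean and error bars the SD; the ssRNase lists lie above the dsRNase lists in number and length and below them in minus-strand share.

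The second comparison asked whether protection recurred at the same positions. Of the sites of one ssRNase list, 22.5% to 82.7% overlapped a site of another ssRNase list by at least 1 nt on the same strand. After the same sites were moved by 200 to 1000 nt, 3.88% to 13.8% did so. For pairs of dsRNase lists the share was 33.5% to 43.0%, on average 8.15 times the share after the shift, against 5.87 times for pairs of ssRNase lists. This order was the opposite against random placement on the chromosome, at 94.8 and 153.0 times. Sites also recurred between nucleases. Between 26.8% and 67.1% of the sites of a dsRNase list overlapped a ssRNase list, on average 4.81 times the share after the shift. In the other direction 6.72% to 13.3% of ssRNase sites overlapped a dsRNase list, 4.84 times the share after the shift. Pairs share lists, so these shares carry no test, and they rise with the length of the list searched.

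**Figure D2:**
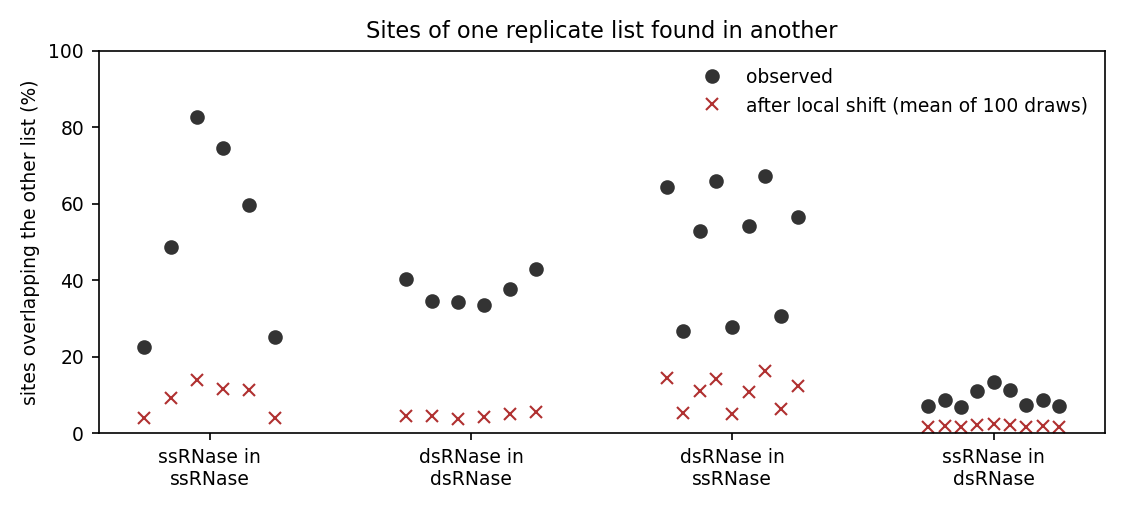
Percent of the sites of one replicate list that overlap another list, for each ordered pair of lists. Circles are observed values and crosses the mean of 100 local shifts; every circle lies above its cross.

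In the merged lists, which carry no replicate error, 38000 of 51403 dsRNase sites (73.9%, 95% exact binomial interval 73.5% to 74.3%) overlapped a merged ssRNase site, against 17.0% after the shift. Of 280954 merged ssRNase sites, 36520 (13.0%, interval 12.9% to 13.1%) overlapped a merged dsRNase site, against 2.99% after the shift. The list over both nucleases held 293016 sites. Of these 12.01% came from both nucleases, 83.4% from ssRNase alone and 4.57% from dsRNase alone. Sites with both nucleases behind them had a median length of 62.0 nt. The intervals cover counting error only.

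A core of 2039 merged sites, 0.696% of the list, had a contributing site in all 6 replicate lists. Their median length was 110.0 nt, against 39.0 nt for merged sites made of a single replicate site. A merged site spans all replicate sites it joins, so a site joined from more lists is longer by construction. The longest of the 2039 sites lay on the plus strand of the mitochondrial genome from 632 to 1925 and spanned 1294 nt, joining 21 replicate sites. Not all of this span was protected in each list. Sites of the ssRNase lists with midpoints from 1001 to 2000 on that strand held 256, 139 and 161 bases. The second longest site was on the minus strand of chromosome X from 73070619 to 73071831, with 1213 nt and 53 replicate sites. The other 3 lay on the plus strand of chromosome 11, from 65191808 to 65192955 (1148 nt), from 65195293 to 65196296 (1004 nt) and from 65267509 to 65268490 (982 nt). Transcripts at these positions were not assigned, since no annotation of this build was used here.

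Protected sequence from the mitochondrial genome made up a far larger part of the dsRNase lists. It held 1.13% ± 0.123 of site bases with dsRNase (SD, n = 3) and 0.0808% ± 0.0278 with ssRNase (SD, n = 3), a ratio of 13.9. In number of bases the lists parted on the plus strand, where the dsRNase lists held 6154 ± 1060 protected bases and the ssRNase lists 898.0 ± 426.5 (SD, n = 3 each), although the dsRNase lists were much shorter overall. On the minus strand the lists held 3614 ± 392.7 bases with dsRNase and 4445 ± 2690 with ssRNase (SD, n = 3 each), which differed by less than the spread between replicates (two-sided exact permutation p = 0.9). As a share of site bases the minus strand was higher with dsRNase too. Its window from 10001 to 20000 held 2581 ± 96.4 bases per 1000000 site bases with dsRNase and 300.4 ± 121.9 with ssRNase (SD, n = 3 each; difference in log2(value + 20) -3.11, limma adjusted p = 0.00509). The window from 1 to 10000 held 1598 ± 261 and 371.0 ± 128 (SD, n = 3 each; difference -2.09, limma adjusted p = 0.00778), and did not pass with equal numbers of sites per strand (limma adjusted p = 0.076). The contig Un_gl000220 took 0.734% ± 0.0982 of site bases with dsRNase and 0.299% ± 0.188 with ssRNase (SD, n = 3 each). In bases the order was the opposite, with 6248 ± 176.3 protected bases on its plus strand with dsRNase and 16327 ± 1342 with ssRNase (SD, n = 3 each). Chromosome X held 4.45% ± 0.282 of site bases with dsRNase and 3.37% ± 0.102 with ssRNase (SD, n = 3 each). Of 28 chromosome and strand shares, 18 reached the smallest possible p of 0.1 (two-sided exact permutation test) and none could pass after Benjamini-Hochberg adjustment, which gave 0.156. Besides the minus-strand share, these were 7 chromosome classes higher with dsRNase and 10 higher with ssRNase.

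**Figure D3:**
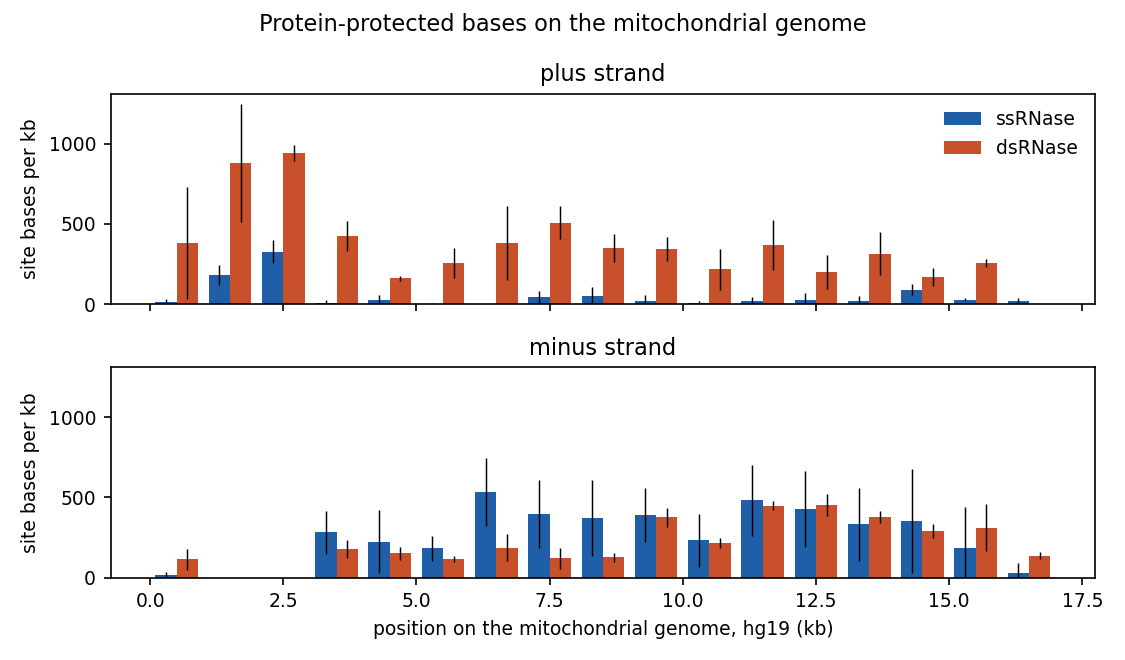
Protected bases per kb along the plus and minus strands of the mitochondrial genome (hg19 position in kb). All bases of a site are counted in the kb that holds its midpoint. Bars are the mean of the 3 lists of each nuclease and error bars the SD; dsRNase bars stand above ssRNase bars over most of the plus strand.

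Sites were not evenly divided between strands. The minus strand held 78.4%, 63.3% and 76.9% of the sites of the 3 dsRNase lists and 56.6%, 58.8% and 58.1% of those of the ssRNase lists. The mean minus-strand share of site bases was 72.9% ± 7.36 with dsRNase and 58.5% ± 3.24 with ssRNase (SD, n = 3 each; two-sided exact permutation p = 0.1). All 3 dsRNase lists lay above all 3 ssRNase lists on 23 of 23 chromosomes (the 22 numbered ones and X), and dsRNase replicate 2 was the lowest of the dsRNase lists on 23 of them.

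To find regions that differed between nucleases, site bases per 1000000 site bases of a list were compared over stranded windows of 10000 bp. Large differences toward dsRNase were on the mitochondrial plus strand. Its window at the start (1 to 10000) held 5346 ± 521 bases per 1000000 with dsRNase and 107.5 ± 36.9 with ssRNase (SD, n = 3 each), a difference of -5.43 (SE 0.255, limma adjusted p = 0.00427) in log2(value + 20), ssRNase minus dsRNase. The second mitochondrial plus-strand window differed by -5.13 (SE 0.24, limma adjusted p = 0.00427). Plus-strand windows on chromosome 1 from 560001 to 570000 and on chromosome 17 from 22020001 to 22030000 followed, at -5.09 and -4.55. The order of the leading windows changed with the scale, and the chromosome 1 window lay beyond both mitochondrial windows with a pseudocount of 5, by number of sites and with scaling within strands. The other 6 of the 10 largest were on the minus strand of chromosomes 20, 3, 14, 17, 6 and 11, with differences from -4.13 to -3.98. These 10 were chosen among windows that passed, so their limma adjusted p, between 0.00427 and 0.00474, adds no support. All 10 also passed with equal numbers of sites per strand drawn from every list. That draw used the same sites, so it is not independent of the choice. Whether the chromosomal windows among them hold nuclear copies of mitochondrial sequence, or reads that map to several places, was not tested. They may therefore not be separate from the mitochondrial windows.

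Toward ssRNase the 10 largest differences ran from 2.84 to 3.48. The leading window was on the plus strand of chromosome 7 from 102090001 to 102100000, with 211 ± 74.7 bases per 1000000 with ssRNase (SD, n = 3) and no site in any dsRNase list (limma adjusted p = 0.00449). In 8 of the 10 windows the dsRNase lists had no site, so that the size of the difference depends on the added constant of 20 and no fold is given. With equal numbers of sites per strand 5 of the 10 passed and 2 were not tested, having sites in fewer than 3 lists there. The 10 windows with the largest mean share all had a higher mean with dsRNase, and 8 of them passed, against 4 with equal numbers of sites per strand. They lay on the mitochondrial genome, on Un_gl000220 (plus strand, from 110001 and from 150001), on the minus strand of chromosome X from 73040001 to 73070000 and on the plus strand of chromosome 11 from 65190001 to 65210000. The 2 chromosome 11 windows did not pass, at -0.88 and -1.13 (limma adjusted p = 0.174 and 0.0695). All these window values are shares of lists of unequal length, and a higher share need not mean more protected bases. In bases the plus strand of Un_gl000220 held 16327 ± 1342 with ssRNase and 6248 ± 176.3 with dsRNase (SD, n = 3 each). The mitochondrial minus strand held 4445 ± 2690 and 3614 ± 392.7 (SD, n = 3 each).

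Over all 31432 windows with a site in at least 3 lists, 10563 passed a limma adjusted p of 0.05, 8349 higher with ssRNase and 2214 higher with dsRNase. With a replicate block in the fit, an alternative fixed beforehand, 0 windows passed (11366 had an unadjusted p below 0.05). The limma adjusted p-values given for windows here and above come from the fit without that block. The count and its split depended on the windows admitted and on the number of sites. Of the windows higher with ssRNase, 94.3% had no site in any dsRNase list. Among windows with a site of both nucleases, 754 of 19860 passed, 132 higher with ssRNase and 622 higher with dsRNase, a choice that by itself removes nearly all calls higher with ssRNase. With equal numbers of sites drawn from every list 765 were higher with ssRNase and 1010 with dsRNase, and with median scaling 11679 and 1132. Without ssRNase replicate 1, 2 or 3 the calls fell to 147, 51 and 45 of the windows that then had a site in at least 3 lists, of which 2, 0 and 0 were higher with ssRNase (2217, 2006 and 2005 windows had an unadjusted p below 0.05). With 2 ssRNase lists left, that filter leaves out every window with ssRNase sites alone. With the windows of all 6 lists kept, a choice made after those counts had been seen, 10017, 12026 and 8611 passed, of which 8336, 10104 and 7141 were higher with ssRNase. The list left out had helped to choose these windows, so these counts do not show that the calls are stable.

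The authors' score was used only within a list. In each of the 6 lists, sites found again in another list of the same nuclease scored higher. A recurring site outscored a non-recurring one with a chance of 0.687 to 0.747 (mean 0.725 ± 0.0206, SD over 6 lists; permutation p = 1e-05 in each list, the smallest that 100000 resamples give). Sites are not independent replicates. Score and length were correlated across sites, with Spearman's rho between 0.365 and 0.441.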

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

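All tests in this part were chosen only after the result was seen. Summed over the mitochondrial genome the 2 nucleases showed opposite strands, which is why this result stands here. The minus strand held on average 82.6% of mitochondrial site bases in the ssRNase lists and 37.2% in the dsRNase lists. In each of the 3 ssRNase lists more bases were protected on the minus strand, and in each of the 3 dsRNase lists more on the plus strand. The dsRNase lean was not even along the genome. Plus-strand sites with midpoints from 1001 to 2000 and from 2001 to 3000 held on average 878.7 and 943.3 bases with dsRNase. No list had minus-strand sites there. In each 1000 bp bin from 11001 on, the dsRNase mean was higher on the minus strand. The strand contrast in bases is thus one of totals. The difference in minus-strand share counts as not tested, since the two-sided exact permutation p of 0.1 is the smallest that 3 against 3 lists allow. By number of sites the dsRNase lists were nearly even, with 48.6% to 55.9% on the minus strand.

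A strand difference that runs through the whole dsRNase lists argues in the wrong direction for this contrast, since it raises the minus strand with dsRNase while the mitochondrial share differed by -45.4 percentage points (dsRNase minus ssRNase). The ssRNase lists held small numbers of mitochondrial sites (67 to 128 per list). The lowest lower 95% exact bound of the ssRNase minus-strand share of sites, 67.7%, lay above the highest upper bound with dsRNase, 64.1%. This argues against counting error alone in the share of sites, if sites are taken as independent. Neighbouring sites may not be, and the bounds do not cover the contrast in bases, so small numbers are not excluded there. Nuclear copies of mitochondrial sequence, reads that map to several places and the nuclease difference itself stay open, and none was tested.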

How the results depend on the processing

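The number of sites, their length, the mitochondrial, minus-strand and Un_gl000220 shares and the score difference kept their direction under all alternatives run; the p of the first 5 is 0.1 at best, so it says nothing of stability. Sizes moved: on the plus and the minus strand alone the site ratio of 5.947 was 9.075 and 4.739, the mitochondrial difference of -1.046 percentage points (ssRNase minus dsRNase) was -2.674 and -0.462, and that of Un_gl000220, -0.434, was -2.123 and -0.0033 (exact permutation p = 0.3 for the last). By number of sites the latter 2 differences were -0.615 and -0.248, and with the better-scoring 50% -1.544 and -0.756. Tests on single strands, within strands, on windows with a site of both nucleases and with the windows of all 6 lists kept were chosen after seeing the data. Where no reason is given, the cause was not tested.

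With an overlap of 50% of the site, ratios to shifted sites became 10.23 (ssRNase in ssRNase), 12.9 (dsRNase in dsRNase), 6.438 (dsRNase in ssRNase) and 7.955 (ssRNase in dsRNase), and shares 32.26% (dsRNase in dsRNase) and 5.771% (ssRNase in dsRNase). With reciprocal overlap the ratios were 14.43, 19.27, 9.699 and 9.718, and shares 27.23% (dsRNase in dsRNase), 27.47% (dsRNase in ssRNase) and 5.162% (ssRNase in dsRNase). Against random placement on the chromosome, which ignores where transcripts are, the ratios were 153.0, 94.8, 99.55 and 101.9. The better-scoring 50% gave 7.209 (ssRNase in ssRNase). Leaving out a list gave 5.282 to 6.411 (ssRNase in ssRNase) and 7.677 to 8.963 (dsRNase in dsRNase).

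For the merged lists (dsRNase in ssRNase, then the reverse) an overlap of 50% gave 67.02% and 8.185% (ratios 5.832 and 7.113), reciprocal overlap 39.68% and 7.26% (8.568 and 8.539), either strand 74.34% and 13.72% (4.197 and 4.28), and random placement ratios of 98.59 and 100.7. Merged lists were not run at the better-scoring 50%.

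The window counts changed most. Of 10563 calls (8349 higher with ssRNase, 2214 with dsRNase, 79.0% ssRNase), windows with a site in all 6 lists gave 1845 (94 and 1751, 5.09%), equal numbers of sites 1775 (765 and 1010, 43.1%), equal numbers per strand 1415 (537 and 878, 38.0%), and windows with a site of both nucleases 754 (132 and 622, 17.5%). The settings that need all 6 lists or both nucleases leave out by construction the windows with no dsRNase site, where most calls higher with ssRNase lay. A pseudocount of 80 gave 5420 higher with ssRNase, and median scaling 1132 higher with dsRNase (91.2% ssRNase). The plus strand alone gave 792 higher with dsRNase, and the minus strand alone 4733 calls (3587 and 1146); these test fewer windows and also scale shares within the strand.

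Leaving out a list, with the filter applied again, gave 45 to 10078 calls (0 to 7618 higher with ssRNase, 45 to 2460 with dsRNase, 0.0% to 75.6% ssRNase). The fall was without ssRNase replicate 1 (147 calls, 1.36% ssRNase), replicate 2 (51, 0.0%) and replicate 3 (45, 0.0%), where windows with ssRNase sites alone no longer pass the filter; the dsRNase calls fell with them, to 145, 51 and 45. Once these counts had been seen, the windows of all 6 lists were kept instead, which gave 10017, 12026 and 8611 calls without an ssRNase list and 8134, 9761 and 8018 without a dsRNase list. Without ssRNase replicate 1, 2 or 3 these held 1681, 1922 and 1470 calls higher with dsRNase, so the calls in both directions depended on the windows admitted. The kept windows were chosen with the list that was left out. Among them, windows with ssRNase sites alone had sites in both remaining ssRNase lists by construction. These counts therefore do not show that the calls are stable. Of the calls higher with ssRNase 94.3% lay in windows with no dsRNase site, while 97.0% of those higher with dsRNase lay in windows with an ssRNase site.

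With the replicate block limma gave 0 calls (0 in either direction; 11366 at an unadjusted p below 0.05), and with equal sites per strand and the block 0 (2682 unadjusted). Deviations of same-numbered lists had correlations of 0.017, -0.063 and -0.034, within the range of -0.1 to 0.093 for lists of different numbers. These values gave no sign of pairing by number. They cannot exclude that lists of one number shared a culture or a batch, so the blocked fit is not set aside. The named windows kept their direction or lay at 0 in every setting run, and 113 of their values no longer passed. The 10 named windows higher with dsRNase, which were chosen for passing in the main setting, passed in each setting run except the 2 with the replicate block. Location in transcripts, base composition, gene lists and the exons-only alternative were not run, since no annotation or sequence of the build was used here. Depth limits all of this: it is unknown, and short lists leave windows empty.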

Other observations

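All tests of explanations in this part were chosen only after the results were seen. Protected sites on facing strands were common with ssRNase. In the ssRNase lists 7.16%, 11.7% and 8.68% of sites overlapped a site of the same list on the other strand, against 1.54%, 1.52% and 1.67% after the local shift. In the dsRNase lists the shares were 0.51%, 0.69% and 0.979%, against 0.304%, 0.489% and 0.616%. The mean was 9.18% ± 2.31 with ssRNase and 0.726% ± 0.237 with dsRNase (SD, n = 3 each; two-sided exact permutation p = 0.1).

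The short ssRNase list held sites that scored well elsewhere. Sites of ssRNase replicate 1 that overlapped replicate 2 had a median score percentile of 80.4 within their list, against 43.7 for the others. In ssRNase replicate 3 these values were 78.3 and 44.1.

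The minus-strand excess of the dsRNase lists may come from a difference between strands in the libraries or in site calling. All 3 dsRNase lists lay above all 3 ssRNase lists on 23 of 23 chromosomes, which such a difference would give. The mitochondrial genome leaned the other way (37.2% of site bases on the minus strand with dsRNase, 82.6% with ssRNase), so a difference acting alike on all sequences is not borne out. The running numbers in the site names were nearly even between strands with dsRNase (50.6%, 48.4% and 49.6% minus), while 9.78%, 7.32% and 10.5% of the minus-strand numbers were listed against 2.75%, 3.99% and 3.11% of the plus-strand ones. With ssRNase 47.8%, 66.2% and 64.7% of the numbers were minus. Of these minus-strand numbers 20.7%, 6.68% and 12.7% were listed, against 14.5%, 9.17% and 16.8% of the plus-strand ones. The smallest difference in minus-strand share over the 23 chromosomes, 10.6 percentage points, follows from the order of the lists on every chromosome. It decides nothing about protection of particular transcripts, which stays open beside the libraries and site calling.

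The windows higher with ssRNase may in part reflect the short dsRNase lists. No dsRNase site lay in 94.3% of them, but a real preference would leave such windows too, so the 2 cannot be told apart from this share. In simulated lists of the real lengths 0.512% of unchanged windows were called higher with ssRNase when 8000 windows were changed and 0.0% when 200 were. In the data 26.6% of all tested windows were called so. In the simulations drawn from ssRNase sites, each dsRNase-like list was a draw from the ssRNase list of the same number. They lacked the variation of the real dsRNase lists, so these rates cannot say how many calls came from list length. With equal numbers of sites per strand drawn from every list 537 windows were called higher with ssRNase, which argues against the number of sites as the cause of every call, though the depth behind the sites is unknown. Of the 10 splits of the 6 lists, 1 (the real one) gave as many calls, both with all sites (10563, highest other 0) and with equal sites per strand (1415, highest other 0). The highest other counts at an unadjusted p below 0.05 in limma were 1270 and 533. With 10 splits the share cannot fall under 0.05.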
